A study of Mus musculus with 10 samples.

How the data were processed

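Kidney messenger RNA of male mice was profiled in 10 libraries, 5 from mice after sham surgery and 5 from mice after kidney ischaemia of 30 min and reperfusion of 24 h (IRI). Per the labels' protocols, libraries were made from 1 µg of total RNA by oligo(dT) selection, fragmentation and random priming, and were sequenced as paired reads of 150 bases. No interval between surgery and sampling was available for the sham libraries, so whether it matched the 24 h of IRI is not known here. The labels do not give the diet of any mouse, and none states outright that each library came from a different mouse, so p-values measure the spread between these libraries.

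The authors deposited 1 table with whole-number counts per gene and FPKM per gene for each library, with the exonic length and coordinates of 55359 genes. Cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and the build GRCm39 are named in the submitters' processing notes, without their roles or settings. Whether the counts used strand is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. Each deposited FPKM equalled count divided by exonic length and library total within 0.005 units or 0.1% (100% of values). Every line of the table had a gene identifier. Symbols were found for 52083 genes by identifier in a reference table of gene names. GC content, used in a check of bias, came from transcripts of build GRCm38, and no coordinate of that build was used. Coordinates are those of the deposited table.

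Genes entered the tests with at least 1 FPKM in 5 or more libraries, which left 13324 genes holding 98.9% to 99.3% of the counts per library. The design fixed before the data were examined named limma on log2(FPKM + 1) as the gene test, because a table of FPKM was expected, and provided for a counts test if the table also held whole counts. It did, and counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with TMM factors, and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. Standard errors of log2 fold changes were computed as the fold change divided by the square root of the F statistic. FPKM is given as mean ± SD of 5 libraries per group. It is scaled by library totals and the fold changes by TMM factors, so ratios of FPKM means differ from the printed fold changes.

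A total of 50 gene lists were fixed before the data were examined. Of these, 48 were tested on log2(FPKM + 1) with limma 3.58.1 (camera, preset correlation 0.01, and again with an estimated correlation). B and plasma cell markers had 2 tested members and T and NK cell markers 0, too few for camera. The design also fixed limma's fry, which does not set a list against other genes. Fry gave adjusted p = 1.13e-08 for tubular injury markers, but also 2.91e-06 for ferroptosis and 3.83e-05 for glycolysis, which camera did not call. With 66.9% of tested genes called, fry sets few lists apart and is not used below. For 13 pairs of lists, the difference in response was tested by an exact two-sided permutation test over all 252 assignments of 5 of 10 libraries, whose smallest p is 0.00794. Fold changes of lists are medians of the edgeR values.

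The rule for named genes, also fixed beforehand, took the 12 higher and 12 lower called genes of largest fold change with a mean of at least 5 FPKM and no overlap between groups, passing over predicted genes and clone names without a gene name, then up to 4 called and 2 uncalled members per list, and a fixed set of genes of methionine and glucose metabolism. By this rule the text names at most the first 3 called members of each list, besides the fixed set, and no uncalled ones. This narrowing was made after values were seen. Other members, some of them uncalled, are named outside the rule, from fits with no filter and from sums of genes below the filter. The result of 1 gene that the rule takes is not reported here. Mat1a and Bhmt of the fixed set were below the filter.

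On simulated counts for 13324 genes with the means and dispersions of the sham libraries and the library sizes of all 10, edgeR recovered 52% of 50 genes changed 1.5-fold, 82% of those changed 2-fold, 96% at 4-fold and 100% at 8-fold, and 5.71% of its calls were false. The real IRI libraries differed more among themselves (chi-square per degree of freedom 14.4 to 109) than the sham libraries did (8.99 to 40.0). The simulation also left most genes unchanged, so it does not test the scaling. These rates may therefore be too favourable for the real comparison. Library totals of 13147899 to 18603272 counts set the precision, and counting intervals cover counting error only. Alternatives were other pseudocounts, filters, scalings, thresholds and tests, a block for the replicate number (a sign-flip test for the pairs of lists), DESeq2 1.42.0, and leaving out each library in turn. Genes with near-identical copies (Hspa1a and Hspa1b, Sprr2f and Sprr2g, Gsta1, Akr1c14 and Akr1c18, Hba-a1, Mettl7a2 and Methig1, ribosomal protein genes with pseudogenes, and mt-Atp6) are uncertain, since the counting could split or drop their reads.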

Results

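Transcript levels were compared between 5 kidneys of mice after sham surgery and 5 kidneys after ischaemia of 30 min followed by reperfusion of 24 h. Library totals were 14858950, 18603272, 16411872, 13199234 and 16592237 counts in sham replicates 1 to 5, and 16268673, 13147899, 17307039, 17045971 and 16833437 in IRI replicates 1 to 5 (difference of means, exact permutation p = 0.841, n = 5 each). The first principal component held 80.2% of the variance and separated the groups, and correlations of log2 CPM were 0.959 to 0.988 within groups and 0.806 to 0.879 between them. IRI replicate 1 lay at -47.6 on the second component and held 2.31% of its counts in mitochondrial rRNA, against 0.214% to 0.450% in the other IRI libraries. Histone and small RNA genes, whose transcripts mostly lack a poly(A) tail, summed to 276 to 354 CPM in sham and 95.4 to 151 CPM in IRI. No IRI library reached the lowest sham value. Whether poly(A) selection or the levels of these RNAs differed between the groups cannot be told apart here. A difference in selection would bear on the comparison of the groups. Every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 8.99 to 109).

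**Figure D1:**
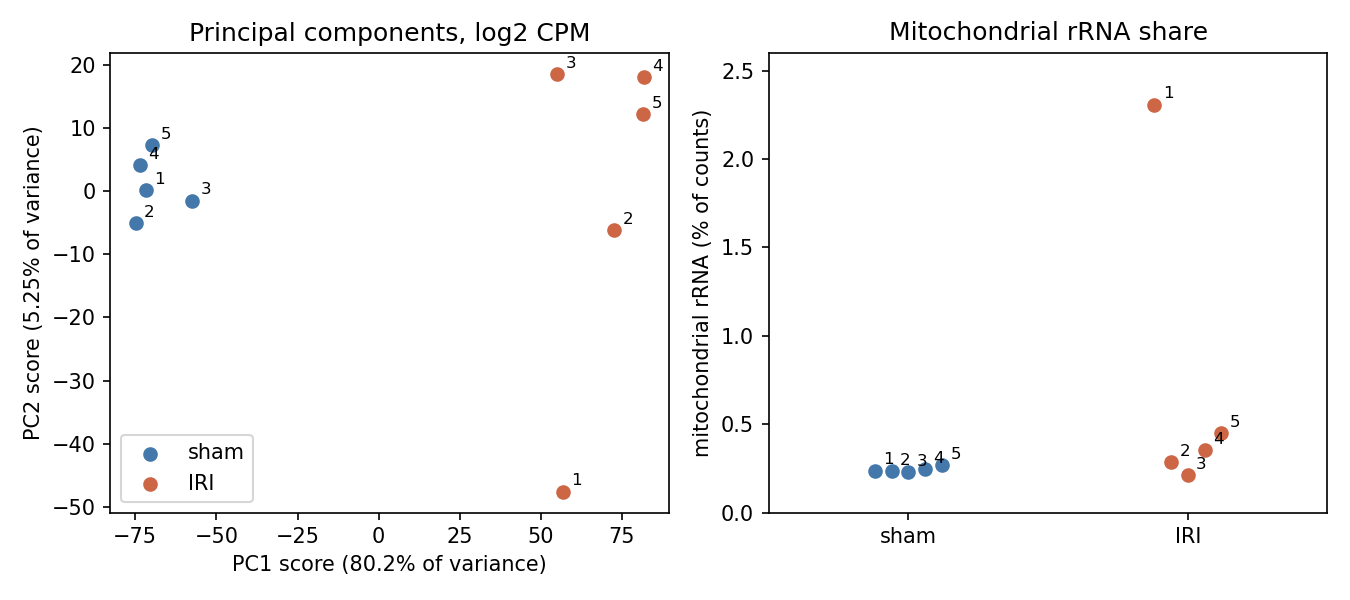
Left, scores of the 10 libraries on the first 2 principal components of log2 CPM, with replicate numbers beside the points; right, the share of counts in mitochondrial rRNA per library. The groups separate on the first component (80.2% of the variance), and IRI replicate 1 stands apart at 2.31% mitochondrial rRNA.

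The main comparison asked which kidney transcripts differed 24 h after reperfusion. Krt20, an epithelial keratin, rose by 10.43 ± 0.49 (log2 fold change ± SE), or 11.53 without sham replicate 3. Its FPKM was 0.212 ± 0.263 in sham and 359 ± 70.7 in IRI (SD, n = 5 each). Lcn2, which encodes the secreted injury marker NGAL, rose from 1.13 ± 0.583 to 1504 ± 504 FPKM, and Havcr1, which encodes KIM-1, from 0.520 ± 0.142 to 345 ± 224 FPKM. Mettl7a2 was among the genes that fell (-6.20 ± 0.46), with 49.1 ± 22.1 FPKM in sham and 0.814 ± 0.498 in IRI. Of 13324 genes tested, 4599 were higher and 4320 lower in IRI by edgeR, with 4405 not called. At least 2-fold, 1589 genes were higher and 1999 lower.

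Further genes of large increase included Sprr2f (10.18), Sprr2g (9.16), Cxcl2 (7.17), Gsta1 (7.12), Retnlg (6.56), Timp1 (6.39) and the metallothionein Mt2 (5.81), all log2 fold changes. Grp had 1 count over the 5 sham libraries and 1838 over the IRI libraries, a ratio of 1524 with a 95% counting interval of 273 to 60226. Its sham count lay in sham replicate 5, without which Grp was at least 402-fold higher, against a floor of 3 counts over the sham group. Further large decreases were those of BC024386 (-5.76), the organic anion transporters Slc22a13 (-5.67) and Slc22a7 (-5.32), Akr1c18 (-5.52), Methig1 (-5.42), the brush border protease Mep1b (-5.20), Cyp7b1 (-5.11), Akr1c14 (-5.03), BC049987 (-5.03), Slc7a13 (-4.98) and Nlrp6 (-4.88). Adjusted p-values of the genes named so far ranged from 5.98e-09 to 3.88e-05 by edgeR. Single libraries moved some of these folds by over 1.5 times: the log2 value of Sprr2f increased by 1.83 without sham replicate 2, Retnlg was at 7.41 without sham replicate 3, Timp1 at 7.10 without sham replicate 5, and Slc22a7 at -5.97 without IRI replicate 2. Leaving out IRI replicate 1 put Cxcl2 at 6.18, Retnlg at 5.89 and BC024386 at -6.64. In the deposited coordinates (GRCm39), Lcn2 lies on chromosome 2 from 32274645 to 32278264, Krt20 on chromosome 11 from 99319229 to 99328976, Havcr1 on chromosome 11 from 46625907 to 46670405 and Mettl7a2 on chromosome 15 from 100251081 to 100259721.

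No IRI value overlapped the sham values in 7370 genes (55.3%), where chance gives 0.794%. Scaling by library totals in place of TMM factors (means 0.916 in sham and 1.09 in IRI) raised the log2 fold changes by a median of 0.25 and gave 6311 higher and 3149 lower genes, so that 66.7% of calls were higher, against 51.6% with TMM.

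**Figure D2:**
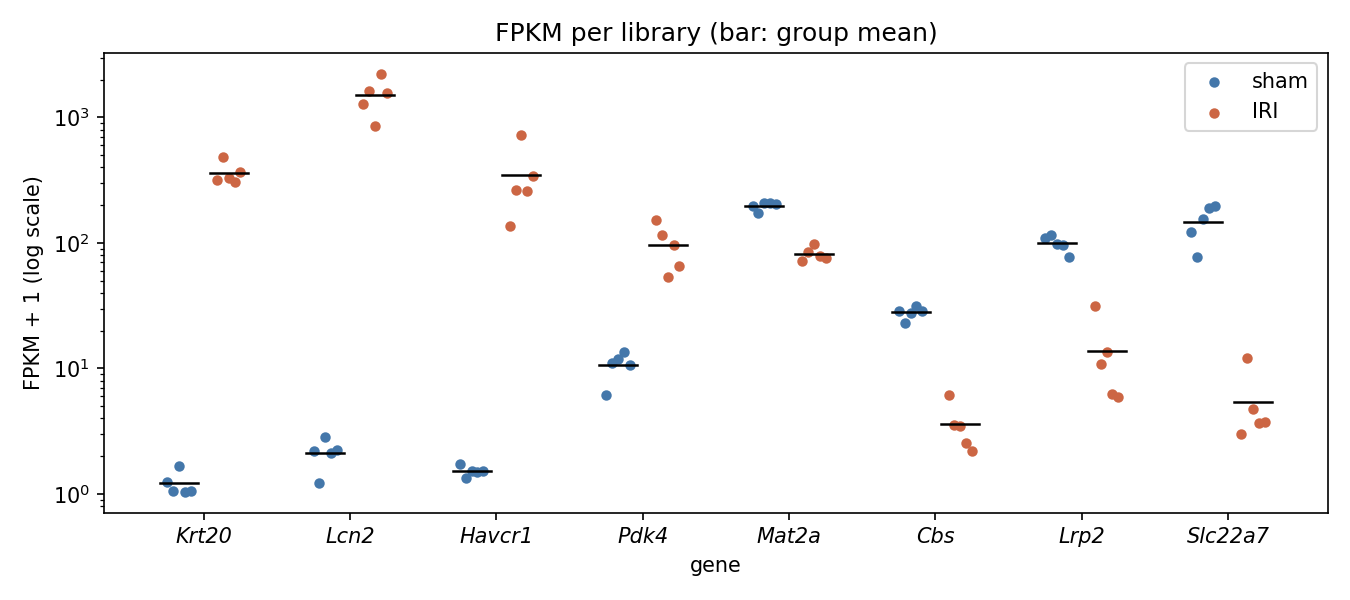
FPKM + 1 on a log scale for 8 genes in each of the 5 sham and 5 IRI libraries, where points are libraries and bars group means. Krt20, Lcn2, Havcr1 and Pdk4 lie higher, and Mat2a, Cbs, Lrp2 and Slc22a7 lower, in all 5 IRI libraries than in all 5 sham libraries.

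Camera called 9 lists higher and 12 lower in IRI with the preset correlation, and 0 in either direction with an estimated correlation. The adjusted p with an estimated correlation is given beside each list that the preset correlation called. The lists had been fixed before the data were examined. Counts of called members stand against shares over all tested genes of 34.5% higher and 32.4% lower. Unless another count is given, adjustment over the list alone called as many members. Members that missed the filter are not counted, and a gene near 0 FPKM in sham passes it only by rising. Lists of which 5 or more members missed it are therefore also given with no filter on low values, by edgeR on all members with counts. So are the ferroptosis, methionine cycle and glycolysis lists, chosen after their values were seen. Other lists with fewer such members also moved with no filter. The median of p53 targets went from 1.07 to 1.45 and that of NAD synthesis from -1.43 to -1.07. Genes named from the fits with no filter were chosen after their values were seen.

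Injury genes rose together. Of 23 tubular injury markers, 22 were higher and 1 was not called, with a median log2 fold change of 3.77 and Krt20, Lcn2 and Havcr1 among them (camera adjusted p = 5.14e-08; adjusted p = 0.182 with an estimated correlation). All 16 tested immediate early and AP-1 genes were higher (median 2.87), among them Fosl1, with 3 sham counts and a ratio of 243 (95% counting interval 82.8 to 1179), Atf3 (5.02 ± 0.57) and Klf6 (3.92 ± 0.24; camera adjusted p = 3.08e-05; adjusted p = 0.383 with an estimated correlation). Of 18 matrix remodelling genes, 16 were higher (median 2.46), among them Mmp7 (2 sham counts, ratio 144, 95% counting interval 39.6 to 1196) and Timp1 (camera adjusted p = 9.64e-06; adjusted p = 0.182 with an estimated correlation). The p53 targets had 14 of 16 members higher and 1 lower, including the cell cycle inhibitor Cdkn1a (4.36 ± 0.28), Gdf15 (3.90 ± 0.22) and Pmaip1 (2.41 ± 0.34; camera adjusted p = 0.00224; adjusted p = 0.257 with an estimated correlation). Of 25 cell cycle genes 13 passed the filter, of which 10 were higher and 0 lower, among them Rrm2 (2.33 ± 0.15), Mcm5 (1.65 ± 0.26) and Mcm3 (1.65 ± 0.19; camera adjusted p = 0.0112; adjusted p = 0.357 with an estimated correlation). With no filter the list gave 14 higher, 1 lower and 10 not called of 25 (median 0.87), the lower one Cenpe (-1.09 ± 0.31). Atf3 was at 4.32 without IRI replicate 1. The ratio of Fosl1 was 608 (95% counting interval 109 to 24058) without sham replicate 4, and that of Mmp7 223 (95% counting interval 39.7 to 8820.2) without sham replicate 2 and 228 (95% counting interval 40.7 to 9038) without sham replicate 5. The 1 lower p53 target was not called lower under library totals.

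Of the inflammatory lists, camera called NF-kB feedback genes, cytokines and chemokines, and neutrophil markers higher, and did not call the monocyte and macrophage, interferon-stimulated, or complement and acute phase lists. The list fixed as NF-kB feedback genes had 13 of 14 members higher (camera adjusted p = 0.00108, and 0.391 with an estimated correlation). Among them were Nfkbiz (2.43 ± 0.22), Birc3 (2.07 ± 0.12) and Socs3 (5.29 ± 0.42), the last better known as a feedback gene of STAT3 signalling. Of 22 cytokines and chemokines 12 passed the filter, of which 9 were higher, among them Cxcl2 (7.17 ± 0.96), Lif (5.65 ± 0.81) and Il11 (4.26 ± 0.61; camera adjusted p = 0.0127; adjusted p = 0.341 with an estimated correlation). With no filter they gave 15 higher, 1 lower and 6 not called of 22 (median 2.64), the lower one Ccl4 (-2.23 ± 0.86), which was no longer called without sham replicate 1, 2 or 4 or without IRI replicate 1, 3, 4 or 5. Of 17 neutrophil markers 7 passed the filter, and these were higher (median 4.62), with Retnlg (6.56 ± 0.88), Clec4d (6.13 ± 0.60) and S100a8 (5.04 ± 0.75; camera adjusted p = 0.0127; adjusted p = 0.257 with an estimated correlation). With no filter neutrophil markers gave 15 higher, 0 lower and 2 not called of 17 (median 4.53), the uncalled ones Ltf (-0.19) and Stfa2 (3.19). Monocyte and macrophage markers gave 5 higher, 1 lower and 5 not called of 11 (median 0.44, camera adjusted p = 0.191), with Chil3 (5.70), Cd14 (3.36) and Itgam (3.14) among those that rose. With no filter they gave 8 higher, 3 lower and 8 not called of 19 (median 0.43), with Cx3cr1 (-2.58) and Ly6c2 (-1.46) lower. Among members that passed the filter, neutrophil markers exceeded monocyte and macrophage markers in response by 1.41 on the log2(FPKM + 1) scale (adjusted exact permutation p = 0.0103, n = 5 each), and with all members and no filter by 0.68 (adjusted exact permutation p = 0.0103). Leaving out IRI replicate 1 lowered the folds of Cxcl2 to 6.18, Lif to 4.42 and Retnlg to 5.89. Folds were higher for Retnlg (7.41) and S100a8 (5.84) without sham replicate 3, Clec4d (6.82) without sham replicate 4 and Chil3 (6.30) without sham replicate 2, and 2 monocyte and macrophage markers were lower without IRI replicate 5. Beside the blood cell markers, hemoglobin genes, which mark retained blood, took 0.0103% ± 0.00233 of counts in sham and 0.0206% ± 0.00521 in IRI (SD, n = 5, exact permutation p = 0.00794). The platelet genes Ppbp (4.49, or 5.48 without sham replicate 5) and Pf4 (2.69) were higher.

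Antigen presentation genes fell. Of 9 tested dendritic cell and MHC class II genes, 6 were lower and 3 not called (median -1.53), with Cd209a (-3.75 ± 0.32), H2-Eb1 (-1.95 ± 0.18) and H2-Ab1 (-1.94 ± 0.17) lowest (camera adjusted p = 0.00862; adjusted p = 0.363 with an estimated correlation). Under library totals 5 were lower and 1 higher. Of 14 B and plasma cell markers, both that passed the filter, the immunoglobulin genes Ighm (-2.23 ± 0.43) and Igkc (-1.96 ± 0.23), were lower, and no T or NK cell marker passed it. With no filter, dendritic cell and MHC class II genes gave 0 higher, 10 lower and 4 not called of 14 (median -1.58), B and plasma cell markers 0 higher, 12 lower and 2 not called of 14 (median -2.10) and T and NK cell markers 0 higher, 9 lower and 9 not called of 18 (median -2.21), the last 1 higher and 8 lower without sham replicate 2. The hemoglobin share of counts beside these falls was 0.0103% ± 0.00233 in sham and 0.0206% ± 0.00521 in IRI (SD, n = 5, exact permutation p = 0.00794).

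The next comparison set nephron segments side by side. All 19 tested markers of proximal tubule segments S1 and S2 were lower, with a median of -2.30. Slc17a3 (-3.48 ± 0.47), the endocytic receptor Lrp2 (-3.16 ± 0.49) and the creatine synthesis enzyme Gatm (-3.08 ± 0.54) were among them (camera adjusted p = 4.60e-08; adjusted p = 0.301 with an estimated correlation). Segment S3 had 12 of 13 markers lower and 1 higher (median -4.01), with Slc22a13, Slc22a7 and Cyp7b1 among those that fell (camera adjusted p = 4.64e-07; adjusted p = 0.257 with an estimated correlation). In response, the mean log2(FPKM + 1) of S1 and S2 markers lay below that of podocytes (difference -2.70), of collecting duct principal cells (-2.71) and of distal convoluted and connecting tubule (-1.84; adjusted exact permutation p = 0.0103 for each, n = 5 per group). It lay above that of S3, with a difference of 0.97 (adjusted exact permutation p = 0.0188), where libraries of the groups overlapped. Lrp2 was at -3.87 and Gatm at -3.98 without IRI replicate 1, and Slc22a7 at -5.97 without IRI replicate 2.

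Against the thick ascending limb the difference was -1.63 (adjusted exact permutation p = 0.0344). It passed the threshold no longer without sham replicate 1 (-1.57), 2 (-1.43), 4 (-1.69) or 5 (-1.70), or with medians over members (-0.59). No other segment list was called, except for the thick ascending limb without sham replicate 2 (camera adjusted p = 0.0369) and the distal convoluted and connecting tubule without IRI replicate 5 (camera adjusted p = 0.0459). Thick ascending limb markers gave 4 higher, 7 lower and 2 not called of 13 (median -0.89, camera adjusted p = 0.0849), with Tmem207 (-3.45), Egf (-3.32) and Cldn10 (-2.49) lower. Distal convoluted and connecting tubule markers gave 3 higher, 8 lower and 3 not called of 14 (median -0.85, camera adjusted p = 0.0687), with Pvalb (-3.82), Klhl3 (-1.95) and Emx1 (-1.78) lower. Principal cells had 4 higher, 1 lower and 7 not called of 12 (median 0.33, camera adjusted p = 0.307), or 3 higher adjusted over the list alone, with Scnn1a (0.69) and St6gal1 (0.85) higher and Hsd11b2 (-0.88) lower, the last not called under library totals (-0.61). For intercalated cells the counts were 3 higher, 7 lower and 4 not called of 14 (median -0.42, camera adjusted p = 0.209), or 4 higher adjusted over the list alone, with Slc4a1 (-4.08), Rhcg (-1.79) and Insrr (-1.69) lower. Podocyte markers had 6 higher, 4 lower and 3 not called of 13 (median 0.29, camera adjusted p = 0.639), with Kirrel (1.56), Podxl (1.09) and Wt1 (1.04) higher. Library totals gave 5 higher and 7 lower for the distal convoluted and connecting tubule, 7 higher and 0 lower for principal cells and 7 higher and 2 lower for podocytes. Principal cells had 8 higher and 0 lower by limma on log2(TPM + 1), and 8 higher without sham replicate 3.

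Endothelial markers gave 9 higher, 1 lower and 6 not called of 16 (median 0.47, camera adjusted p = 0.0565), with Nos3 (1.87), Flt1 (0.97) and Cdh5 (0.87) higher. That list was called without sham replicate 5 (camera adjusted p = 0.0391) and without IRI replicate 1 (camera adjusted p = 0.0224). Among fibroblast and pericyte markers the counts were 4 higher, 1 lower and 6 not called of 11 (median 0.74, camera adjusted p = 0.389), with Tagln (2.41), Acta2 (1.96) and Ren1 (1.69) higher. Without IRI replicate 1, whose fibroblast score was 2.88 against 4.05 to 4.44 in the other IRI libraries, 8 were higher. With library totals 7 fibroblast and pericyte markers were higher, and endothelial markers had 12 higher and 0 lower.

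**Figure D3:**
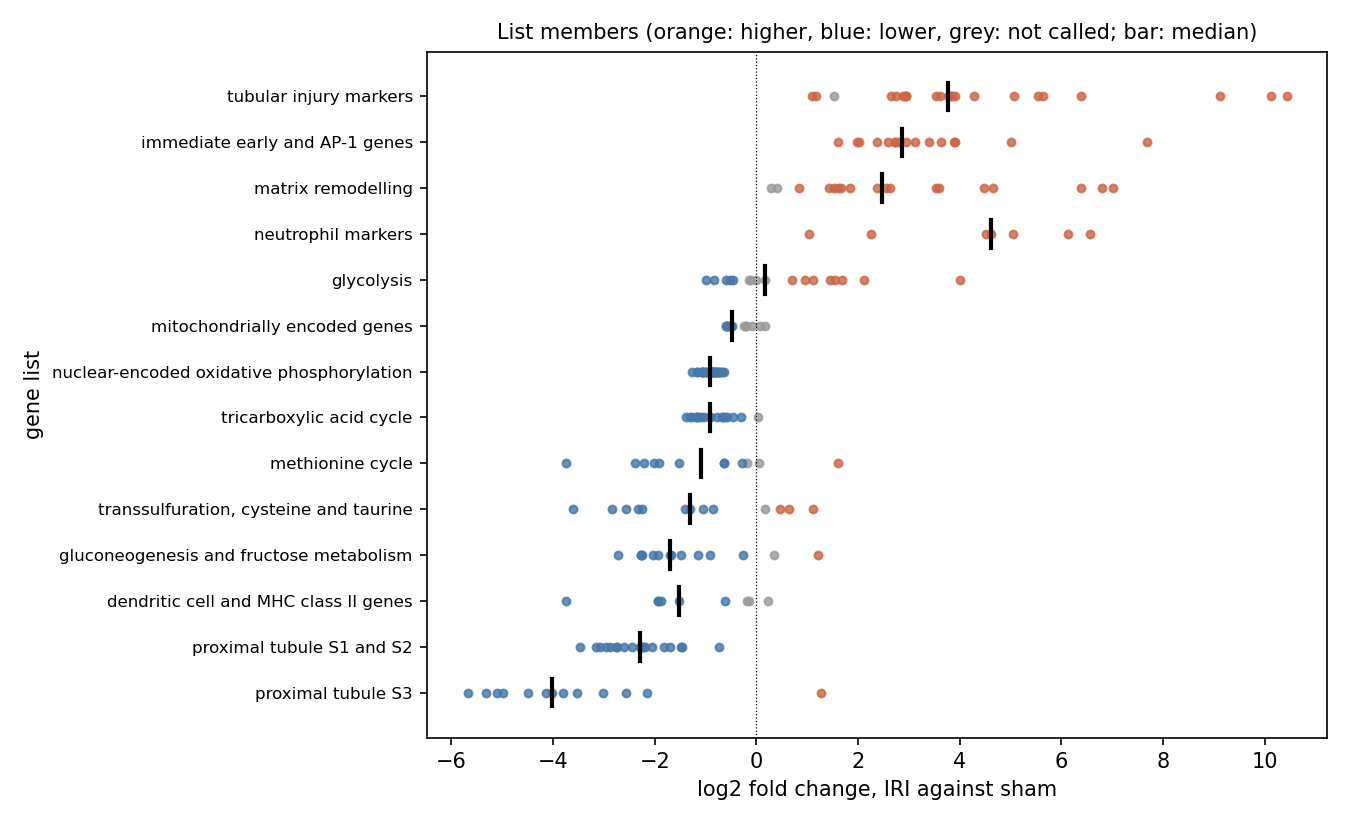
Log2 fold changes (IRI against sham) of those members of 14 gene lists that passed the filter, where each point is a gene, orange is higher, blue lower and grey not called, and the bar is the list median. Medians run from 4.62 for neutrophil markers to -4.01 for proximal tubule S3.

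Methionine metabolism was compared because the series concerns methionine and glucose oxidation. Mat2a, which makes S-adenosylmethionine, fell by 1.53 on the log2 scale with TMM factors. Its FPKM, scaled by library totals, was 197 ± 14.1 in sham and 81.2 ± 10.0 in IRI (SD, n = 5). Of 12 tested methionine cycle genes, 9 were lower and 1 higher (median -1.09), with Bhmt2 (-3.75 ± 0.44), Gamt (-2.39 ± 0.38), Gnmt (-2.21 ± 0.30) and Ahcy (-2.02 ± 0.14) among those that fell (camera adjusted p = 0.00294; adjusted p = 0.182 with an estimated correlation). Transsulfuration, cysteine and taurine genes had 9 of 13 members lower and 3 higher (median -1.31), including Cbs (-3.60 ± 0.37), Csad (-2.85 ± 0.17) and Cth (-2.56 ± 0.25; camera adjusted p = 0.00516; adjusted p = 0.257 with an estimated correlation). The scores of these lists changed by -0.93 and -0.93, and their difference passed no threshold (exact permutation p = 1.00). With no filter, 3 more members entered the methionine cycle score and 1 the transsulfuration score. The difference of scores was then 0.14 (adjusted exact permutation p = 0.0238). Members of low FPKM change little on the log2(FPKM + 1) scale and draw a mean score toward no change. This difference is therefore not read as one in response. Library totals gave 2 higher and 8 lower methionine cycle genes. By edgeR with no filter the methionine cycle list gave 2 higher, 9 lower and 4 not called of 15 (median -0.63). Beside these falls, markers of the proximal tubule had medians of -2.30 in S1 and S2 and -4.01 in S3.

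Methionine salvage and polyamine genes gave 8 higher, 4 lower and 2 not called of 14 (median 0.32, camera adjusted p = 0.399), with Smox (2.40 ± 0.12) and Srm (0.93 ± 0.12) higher and Odc1 (-1.67 ± 0.25) lower. The methionine cycle lay below this list in response, with a difference of -1.29 (adjusted exact permutation p = 0.0103). Methionine and neutral amino acid transporters had 4 higher, 7 lower and 1 not called of 12 (median -0.87, camera adjusted p = 0.215), or 8 lower adjusted over the list alone, with Slc7a5 (3.05 ± 0.23) higher and Slc6a20b (-3.60 ± 0.52) and Slc3a1 (-2.59 ± 0.29) lower. Folate and serine one-carbon genes had 10 of 18 members lower and 4 higher, with Ftcd (-3.82 ± 0.38) and Dmgdh (-2.89 ± 0.33) lower and Mthfd1l (3.62 ± 0.24) higher (camera adjusted p = 0.0143; adjusted p = 0.257 with an estimated correlation). This call ended with median-of-ratios scaling (adjusted p = 0.0635), quantile normalization (0.0522) and TMM log2 CPM (0.0580). Slc6a20b was at -4.35 without IRI replicate 1, and salvage and polyamine genes had 10 higher and 2 lower by limma on log2(TPM + 1).

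Nuclear genes of mitochondrial energy metabolism fell. Markers of the proximal tubule, a segment rich in mitochondria, fell with them, with medians of -2.30 in S1 and S2 and -4.01 in S3. All 31 tested nuclear-encoded oxidative phosphorylation genes were lower (median -0.91), including Sdhb (-1.28 ± 0.13), Sdha (-1.17 ± 0.14) and Ndufs1 (-1.16 ± 0.14; camera adjusted p = 9.18e-11; adjusted p = 0.301 with an estimated correlation). The tricarboxylic acid cycle had 17 of 18 genes lower (median -0.92), with Idh2 (-1.40 ± 0.11) and Suclg1 (-1.31 ± 0.13) beside Sdhb (camera adjusted p = 1.10e-06; adjusted p = 0.257 with an estimated correlation). Of 25 fatty acid oxidation genes, 19 were lower and 2 higher, or 20 and 3 adjusted over the list alone, with Acadm (-2.58 ± 0.17), Hadh (-1.71 ± 0.17) and Ehhadh (-1.61 ± 0.26) lower (camera adjusted p = 0.000170; adjusted p = 0.387 with an estimated correlation). Mitochondrially encoded genes gave 0 higher, 7 lower and 6 not called of 13 (median -0.48, camera adjusted p = 0.144), with mt-Nd4 (-0.58 ± 0.13), mt-Nd3 (-0.60 ± 0.15) and mt-Atp6 (-0.60 ± 0.21) lower, but 1 lower under library totals and 0 by limma on log2(TPM + 1). mt-Atp6 was not called without sham replicate 5 (-0.36) or IRI replicate 5 (-0.51). Nuclear-encoded genes lay below mitochondrially encoded genes in response, with a difference of -0.58 (adjusted exact permutation p = 0.0103). Under library totals the tricarboxylic acid cycle had 1 higher and 15 lower, and fatty acid oxidation 4 higher and 16 lower.

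Genes of glucose metabolism changed in both directions. Glycolysis genes gave 8 higher, 5 lower and 4 not called of 17 (median 0.17, camera adjusted p = 0.460), with Hk2 (4.00 ± 0.46), Eno2 (2.11 ± 0.27), Pkm (1.68 ± 0.18) and Slc2a1 (1.45 ± 0.21) higher and Ldha (-0.46 ± 0.11) lower. Gluconeogenesis and fructose genes had 12 of 14 members lower and 1 higher (median -1.69), with G6pc (-2.73 ± 0.54), Fbp1 (-2.27 ± 0.37) and Slc37a4 (-2.27 ± 0.27) lower (camera adjusted p = 0.000526; adjusted p = 0.301 with an estimated correlation). Glycolysis exceeded gluconeogenesis by 1.88, the tricarboxylic acid cycle by 1.19 and fatty acid oxidation by 1.14 in response (log2 units; adjusted exact permutation p = 0.0103 for each, n = 5 per group). Pyruvate oxidation genes gave 1 higher, 7 lower and 4 not called of 12 (median -0.47, camera adjusted p = 0.0543), with the carrier subunits Mpc2 (-1.36 ± 0.12) and Mpc1 (-0.49 ± 0.13), Pdha1 (-0.62 ± 0.09) and Pdp2 (-1.75 ± 0.21) lower and Pdp1 (1.19 ± 0.17) higher. Of the pyruvate dehydrogenase kinases, which inhibit the complex, 2 were higher and 2 lower, with Pdk4 at 3.08 ± 0.33, Pdk2 at -1.77 ± 0.12 and Pdk3 at -1.61 ± 0.14. The kinases had a median of -0.54 and a mean of 0.05 (camera adjusted p = 0.428). Pyruvate oxidation lay below the kinases in response, with a difference of -0.47 (adjusted exact permutation p = 0.0103), which turned to 0.02 with medians over members. The pyruvate oxidation list was called without sham replicate 5 (camera adjusted p = 0.0362) and without IRI replicate 1 (camera adjusted p = 0.0393). Ldha (-0.21) and Mpc1 (-0.24) were not called under library totals, nor Pdha1 (-0.13) by limma after quantile normalization. Library totals gave 9 higher and 3 lower for glycolysis, 2 higher and 11 lower for gluconeogenesis and 2 higher and 6 lower for pyruvate oxidation, and limma on log2(TPM + 1) gave 12 higher and 2 lower for glycolysis and 3 higher and 4 lower for pyruvate oxidation. G6pc was at -3.49 without IRI replicate 1, and 2 gluconeogenesis genes were higher without IRI replicate 1 or 2. With no filter glycolysis gave 10 higher, 5 lower and 6 not called of 21 entries for 20 members (median 0.72). The proximal tubule, where the kidney makes glucose, had marker medians of -2.30 in S1 and S2 and -4.01 in S3.

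Of the other metabolic lists, NAD synthesis had 12 of 15 members lower and 2 higher, with Ido2 (-4.89 ± 0.43), Acmsd (-3.89 ± 0.56) and Kmo (-3.18 ± 0.33) lower (camera adjusted p = 0.000249; adjusted p = 0.257 with an estimated correlation). Cholesterol synthesis had 11 of 18 lower and 2 higher, with Cyp51 (-2.71 ± 0.24), Idi1 (-2.49 ± 0.20) and Hmgcs1 (-2.38 ± 0.19) lower (camera adjusted p = 0.0157; adjusted p = 0.414 with an estimated correlation). Under library totals 6 were higher and 10 lower, and 4 were higher without sham replicate 1. The pentose phosphate pathway gave 6 higher, 1 lower and 2 not called of 9 (median 0.40, camera adjusted p = 0.175), with Pgd (1.33 ± 0.10) and G6pdx (1.09 ± 0.13) higher and Rpe (-0.94 ± 0.10) lower. Ribosomal proteins, some of whose reads may belong to pseudogenes, had 15 of 22 members higher (median 0.36), and 22 under library totals (median 0.62). Rpl13 (1.14 ± 0.16), Rpl27 (1.02 ± 0.11) and Rps27a (0.87 ± 0.19) were highest (camera adjusted p = 0.000906, and 0.534 with an estimated correlation). Acmsd was at -4.85 without IRI replicate 1, and 1 NAD synthesis gene was higher without sham replicate 2 or 5 or IRI replicate 2, 4 or 5. The NAD synthesis list also holds NAD users such as Sirt3, and Acmsd, whose enzyme leads an intermediate away from NAD. The fall of the list is therefore not one of synthesis genes alone. Beside it, proximal tubule markers had medians of -2.30 in S1 and S2 and -4.01 in S3.

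Stress lists that camera did not call held members called in both directions, where 34.5% of all tested genes were higher and 32.4% lower. Members were named by the size of their fold change, so those named need not show the direction of a list. Among NRF2 targets the counts were 11 higher, 3 lower and 4 not called of 18 (median 0.85, camera adjusted p = 0.0834), or 4 lower adjusted over the list alone, with Gsta1 (7.12 ± 0.56), Srxn1 (3.28 ± 0.11) and Hmox1 (2.50 ± 0.19) higher. Heat shock genes and chaperones gave 7 higher, 1 lower and 6 not called of 14 (median 0.78, camera adjusted p = 0.361), with the near-identical pair Hspa1a (5.69 ± 1.14) and Hspa1b (4.60 ± 1.10), and Hspb1 (3.60 ± 0.29) higher. Leaving out IRI replicate 1 lowered Hspa1a to 3.41 and Hspa1b to 2.70 and gave 6 higher and 4 lower members, while the 1 lower member was not called without IRI replicate 2, 3, 4 or 5. Hspa1b was at 5.73 without sham replicate 3. The unfolded protein response and ATF4 list had 11 higher, 5 lower and 1 not called of 17 (median 0.76, camera adjusted p = 0.307), with Trib3 (3.54), Atf5 (2.13) and Asns (2.09) higher. Ferroptosis and glutathione genes gave 7 higher, 7 lower and 0 not called of 14 (median 0.02, camera adjusted p = 0.937), with Ptgs2 (4.17), Gch1 (2.78) and Acsl4 (2.07) higher. Library totals gave 7 higher and 4 lower, and limma on log2(TPM + 1) 7 higher and 3 lower. With no filter this list gave 9 higher, 7 lower and 0 not called of 16 (median 0.52). Slc7a11 (4.66 ± 0.52), with 23 sham counts and 704 IRI counts, was among the higher members. It had missed the filter and also belongs to the NRF2 and ATF4 lists. Ptgs2 was at 3.02 without IRI replicate 1 and 4.77 without sham replicate 3. For cell death genes the counts were 10 higher, 2 lower and 4 not called of 16 (median 0.59, camera adjusted p = 0.0565), or 12 higher adjusted over the list alone, with Mlkl (3.48), Ripk3 (3.24) and Il1b (2.77) higher. Camera called this list without sham replicate 5 (adjusted p = 0.0447) and without IRI replicate 1 (adjusted p = 0.0434). Hypoxia and HIF targets had 5 higher, 8 lower and 3 not called of 16 (median -0.50, camera adjusted p = 0.249), with Hk2, Adm (1.75) and Slc2a1 higher, and a mean of 0.01. Under library totals the unfolded protein response and ATF4 list had 11 higher and 3 lower, and cell death genes 12 higher and 1 lower.

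In the remaining lists the circadian clock gave 8 higher, 3 lower and 4 not called of 15 (median 0.46, camera adjusted p = 0.331), with Hlf (-2.40) lower and Cry1 (1.96) and Bhlhe40 (1.78) higher. Complement and acute phase genes had 5 higher, 4 lower and 5 not called of 14 (median 0.03, camera adjusted p = 0.879), with Lcn2 and Hp (2.82) higher and Cfb (-2.09) lower. Library totals gave 5 higher and 2 lower, limma on log2(TPM + 1) 5 higher and 1 lower, and Hp was at 3.69 without sham replicate 3. With no filter they gave 7 higher, 5 lower and 8 not called of 20 (median 0.31). Interferon-stimulated genes gave 4 higher, 3 lower and 13 not called of 20 (median -0.01, camera adjusted p = 0.891), with Oasl1 (3.44) and Ddx58 (1.04) higher and Ifi44 (-1.22) lower. Camera's direction for that list was up, its mean was 0.13, and its median was 0.24 under library totals, with 8 higher and 3 lower. Without IRI replicate 3, 5 of its members were lower. Erythrocyte genes had 3 higher, 1 lower and 3 not called of 7 (median 0.66, camera adjusted p = 0.806), with Hba-a1 (0.86) and Hbb-bs (0.68) higher and Slc4a1 lower, a gene that intercalated cells also use, and the mean of the list was -0.09. By limma on log2(TPM + 1), 5 were higher. Platelet genes had 2 higher, 1 lower and 0 not called of 3 (median 2.69, camera adjusted p = 0.581), with Ppbp (4.49) and Pf4 (2.69) higher and Itga2b (-0.81) lower, the last not called under library totals (-0.56). Ppbp was at 5.48 without sham replicate 5, and with no filter the platelet list gave 2 higher, 1 lower and 5 not called of 8 (median 0.90). Adipose, liver and adrenal transcripts gave 2 higher, 1 lower and 0 not called of 3 (median 0.78, camera adjusted p = 0.857), with Ttr (-2.16) lower and Star (0.78) and Alb (1.28) higher, while camera's direction was down and the mean -0.03. With no filter they gave 4 higher, 4 lower and 7 not called of 15 (median 0.81). Alb was not called without IRI replicate 1 (0.61), without IRI replicate 2 (1.19) or without sham replicate 2 (1.27), 3 (1.29), 4 (1.25) or 5 (1.28).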

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

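The tests of mitochondrial mRNA, retained blood and library scaling were chosen after the results they measure had been seen. A library was marked where its gap to the nearest library of its group, divided by the group's range, passed Dixon's 95% value for 5 libraries. This held for 26 of 440 groups of values tested, where 1 in 20, or 22, would be marked by chance. The ratios follow in parentheses. For IRI replicate 2 these were the library total (0.750). For IRI replicate 1 these were the mitochondrial rRNA share (0.887), the score of complement and acute phase (0.830), the score of fibroblasts and pericytes (0.746), Timp1 (0.760), Ptgs2 (0.861), Pmaip1 (0.822), Lif (0.821), Kirrel (0.715). For sham replicate 3 these were the score of heat shock and chaperones (0.798), the score of hypoxia and HIF targets (0.811), the score of collecting duct principal cells (0.756), the score of NAD synthesis (0.746), Hk2 (0.764), Bhmt2 (0.749). For sham replicate 1 these were the score of cell cycle and mitosis (0.810). For sham replicate 2 these were the score of proximal tubule S3 (0.767), Sprr2f (0.739), Slc22a13 (0.811), Mcm3 (0.724). For IRI replicate 3 these were Sprr2f (0.848), Pkm (0.773), Pdp1 (0.723). For sham replicate 5 these were Grp (1.00), Sdha (0.721), mt-Atp6 (0.760).

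The share of mitochondrial rRNA in IRI replicate 1 was 7.23 times the median of the other IRI libraries. More mitochondrial RNA of every kind would raise the mRNAs too, but their median ratio in that library was 1.01 over 13 genes (lowest 0.864, highest 1.44). Weaker poly(A) selection would raise histone and small RNA genes, whose summed CPM was 1.29 times the median of the others and below that of IRI replicate 2 (143 against 151). Neither test gave the value its explanation needs, and what set this library apart stays open. No other biological explanation was tested.

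The fall of antigen presentation and B cell genes was weighed against blood, scaling and cell number. Less retained blood would lower erythrocyte genes, but their median log2 fold change was 0.66. Under 5 scalings the MHC class II and dendritic cell median was at most -1.18. The 12 B and plasma cell genes below the filter, not used in the gene tests, had a summed CPM in IRI 0.351 times that of sham (exact permutation p = 0.00794, n = 5), and the T and NK cell list 0.620 times (exact permutation p = 0.00794, n = 5). Members went both ways. Of the T and NK cell list, Lck, Thy1 and Eomes, singled out after their values were seen, rose, to 1.58 times the sham sum, and held 428 of 594 IRI counts, and the other 15 fell to 0.243 times. Of the B and plasma cell genes Fcmr rose to 2.02 times and the other 11 fell to 0.286 times. By edgeR with no filter, none of these rises was called, and 10 of the 12 and 9 of the 18 were lower, or 8 lower and 1 higher of the 18 without sham replicate 2. Igkc was at 9.86 ± 2.58 FPKM in sham and 3.03 ± 0.638 in IRI. Fewer lymphocytes per unit of kidney RNA after IRI is a hypothesis that the values of the members that fell may reflect. The members that rose do not follow it, and lower transcript levels per cell stay open.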

How the results depend on the processing

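DESeq2, library totals, the fit without mitochondrial rRNA genes, TMM log2 CPM for lists and contrasts with no filter were added after seeing the data. Limma on log2(FPKM + 1), the gene test fixed beforehand for a table without counts, became an alternative once counts were seen, and called 6296 genes higher and 3202 lower. Without each library in turn edgeR called 4352 to 4682 genes higher and 4044 to 4410 lower, and DESeq2 called 4504 and 4493, with 15 genes left without an adjusted p. Of 8919 calls, 8791 were shared with DESeq2, 7800 with limma and 7748 with library totals. Counts moved by over 1.5 times with a filter of 5 FPKM (3044 higher, 2842 lower, 889 at least 2-fold higher, 1244 at least 2-fold lower) and with no filter (2955 at least 2-fold higher, 3326 at least 2-fold lower), where fewer and more genes were tested. They also moved with limma on log2(TPM + 1) (2841 lower, 1308 at least 2-fold lower), on log2(FPKM + 1) (1217 at least 2-fold lower), without trend (1217 at least 2-fold lower) and with array weights (1294 at least 2-fold lower), and with the rank-sum test (1204 at least 2-fold lower); the cause was not tested.

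Replicate numbers did not pair the libraries: correlations of same-numbered libraries were 0.06, -0.13, -0.25, 0.01 and -0.13, and 0 of 5 correlated best with their own number. With a replicate block edgeR called 4221 higher and 4097 lower. The sign-flip test of 5 same-numbered differences cannot give a p under 0.0625, so no contrast could pass, with differences as in the unblocked test: proximal tubule S1 and S2 minus thick ascending limb -1.63, proximal tubule S1 and S2 minus distal convoluted and connecting tubule -1.84, proximal tubule S1 and S2 minus collecting duct principal cells -2.71, proximal tubule S1 and S2 minus podocytes -2.70, proximal tubule S1 and S2 minus proximal tubule S3 0.97, neutrophil markers minus monocyte and macrophage markers 1.41, glycolysis minus fatty acid oxidation 1.14, glycolysis minus tricarboxylic acid cycle 1.19, glycolysis minus gluconeogenesis and fructose metabolism 1.88, pyruvate oxidation minus pyruvate dehydrogenase kinases -0.47, nuclear-encoded oxidative phosphorylation minus mitochondrially encoded genes -0.58, methionine cycle minus methionine salvage and polyamines -1.29. Lists newly past the threshold with the block were apoptosis, necroptosis and pyroptosis (0.0437), endothelium (0.0335), and of the named genes Alb (0.90) and mt-Atp6 (-0.56) were not called.

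With an estimated correlation 0 lists were higher and 0 lower, and the adjusted p rose above the threshold for tubular injury markers (0.182), immediate early and AP-1 genes (0.383), p53 targets (0.257), cell cycle and mitosis (0.357), cytokines and chemokines (0.341), NF-kB feedback genes (0.391), neutrophil markers (0.257), dendritic cell and MHC class II genes (0.363), proximal tubule S1 and S2 (0.301), proximal tubule S3 (0.257), matrix remodelling (0.182), methionine cycle (0.182), transsulfuration, cysteine and taurine (0.257), folate and serine one-carbon metabolism (0.257), gluconeogenesis and fructose metabolism (0.301), tricarboxylic acid cycle (0.257), fatty acid oxidation (0.387), nuclear-encoded oxidative phosphorylation (0.301), NAD synthesis (0.257), cholesterol synthesis (0.414), ribosomal proteins (0.534). Lists past the threshold only under an alternative were, with median-of-ratios scaling, NRF2 targets (0.0306), apoptosis, necroptosis and pyroptosis (0.0297), endothelium (0.0352), pyruvate oxidation (0.0297), mitochondrially encoded genes (0.0417); with quantile normalization, NRF2 targets (0.0192), apoptosis, necroptosis and pyroptosis (0.0455), endothelium (0.0397); with TMM log2 CPM, NRF2 targets (0.0357), apoptosis, necroptosis and pyroptosis (0.0295), endothelium (0.0383), pyruvate oxidation (0.0309), mitochondrially encoded genes (0.0460); and with no filter, which gave 14 higher lists, unfolded protein response and ATF4 targets (0.0439), NRF2 targets (0.00232), apoptosis, necroptosis and pyroptosis (0.00250), endothelium (0.00239), pyruvate oxidation (0.0196), pentose phosphate pathway (0.0196). With no filter, B and plasma cell markers (0.000124) and T and NK cell markers (0.00239) were also past the threshold, both lower. These lists had too few members for camera in the main test. The call of folate and serine one-carbon metabolism ended with median-of-ratios (0.0635), quantile (0.0522) and TMM log2 CPM scaling (0.0580). Uncalled lists changed direction with quantile normalization (interferon-stimulated genes (0.997)), median-of-ratios scaling (adipose, liver and adrenal transcripts (0.959)) and TMM log2 CPM (adipose, liver and adrenal transcripts (0.950)). Leaving out 1 library changed the call or direction of apoptosis, necroptosis and pyroptosis (0.0434 to 0.0830), distal convoluted and connecting tubule (0.0459 to 0.121), endothelium (0.0224 to 0.0733), ferroptosis and glutathione defence (0.860 to 1.00), interferon-stimulated genes (0.672 to 0.955), pyruvate oxidation (0.0362 to 0.0668), thick ascending limb (0.0369 to 0.168), given as the range of the adjusted p, and of methionine cycle minus transsulfuration, cysteine and taurine (-0.0212 to 0.0237), proximal tubule S1 and S2 minus thick ascending limb (-1.98 to -1.39), given as the range of the difference. With medians over members the thick ascending limb contrast was -0.59 and the pyruvate oxidation contrast 0.0187. The uncalled contrast of methionine cycle minus transsulfuration, cysteine and taurine changed sign with pseudocount 0.1 (0.0268), TPM (0.00771), median-of-ratios scaling (0.0241), medians (0.148) and no filter (0.144, adjusted p = 0.0238, past the threshold). In the contrast with no filter, the low members that it added draw the scores toward no change. The other causes were not tested. Of the named genes no fold change reversed, and 53 of their values under alternatives lost the call. Apart from the fixed set they had been picked as called genes of large fold change, so few could reverse. Of all 8919 calls, the sign changed for 303 by limma on log2(TPM + 1), 149 with array weights and 70 with library totals. After quantile normalization 27 changed sign, and 2 were called in the opposite direction. Counts of called list members moved by over 1.5 times for 21 lists with library totals, 17 with a filter of 5 FPKM, 17 by the rank-sum test, 11 at an adjusted p under 0.01, 5 with the block, 2 with no filter (of members that passed the main one) and 1 by DESeq2. By limma this held for 22 lists on log2(TPM + 1), 18 on log2(FPKM + 1), 16 and 17 with pseudocounts of 0.1 and 0.5, 17 without trend, 21 with array weights and 5 after quantile normalization. Depth limits genes under 1 FPKM.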

Other observations

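The gene families below and the test of sex-biased genes were chosen after the genes of largest change and the list results had been seen. Tubulins rose, with 9 higher and 0 lower of 10 (median 2.16; camera adjusted p = 0.000203; adjusted p = 0.314 with an estimated correlation). Actins and Arp2/3 subunits had 9 higher and 0 lower of 11 (median 0.65; camera adjusted p = 0.00157; adjusted p = 0.379 with an estimated correlation). Ribosome biogenesis factors gave 32 higher and 5 lower of 42 (median 0.59; camera adjusted p = 6.47e-05; adjusted p = 0.262 with an estimated correlation), and cytosolic ribosomal proteins 43 higher and 3 lower of 79 (median 0.36; camera adjusted p = 6.47e-05; adjusted p = 0.539 with an estimated correlation). Mitochondrial ribosomal proteins moved the other way, with 6 higher and 63 lower of 81 (median -0.47; camera adjusted p = 6.47e-05; adjusted p = 0.539 with an estimated correlation). Peroxins, which build peroxisomes, had 0 higher and 15 lower of 16 (median -0.53; camera adjusted p = 0.000283; adjusted p = 0.262 with an estimated correlation). UDP-glucuronosyltransferases gave 0 higher and 8 lower of 9 (median -2.50; camera adjusted p = 0.000130; adjusted p = 0.262 with an estimated correlation) and solute carriers 57 higher and 155 lower of 261 (median -0.64; camera adjusted p = 1.85e-05; adjusted p = 0.262 with an estimated correlation). Beside the families that fell, proximal tubule markers had medians of -2.30 in S1 and S2 and -4.01 in S3. Camera's tests ran over 28 families, and the medians of those named here had the same sign under library totals, the other scaling run for them. That scaling gave 68 higher and 1 lower cytosolic ribosomal proteins, 9 and 32 mitochondrial ones, 35 and 0 ribosome biogenesis factors, and 0 and 8 peroxins.

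A split of the 10 libraries by chance was set against the real one. Of 100 splits drawn, 1 gave as many genes as the real split by edgeR (8919), the real one itself, and the highest of the others gave 0 (at most 5249 at an unadjusted p under 0.05, and 1 by limma). This rank, the best that 100 splits can give, argues against a chance assignment of the libraries. It does not bear on a difference in handling that followed the groups. The other splits each mix sham and IRI libraries, so their low counts show no more than the rank does. After removing each library's trend in gene length and GC content, 93.6% of the calls were left with the same direction, and after thinning every library to 13147899 counts 98.1%. Trends in length and GC content do not account for the calls as a whole. Library totals hardly differed between the groups (exact permutation p = 0.841), so thinning could remove few calls and is a weak test of depth.

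A hypothesis on the fall of proximal tubule genes is that androgen-dependent expression was lost in these male kidneys. Of 16 genes listed from background knowledge as male-biased, 15 were lower, with a change in score of -2.78. Of 10 female-biased genes 6 were lower and 4 higher, with a change of -1.15. The score of male-biased minus female-biased genes differed by -1.63 between IRI and sham (exact permutation p = 0.00794, n = 5), and by -1.61 on log2 CPM. Scores are means over genes. The median log2 fold changes were -2.865 and -1.999, a gap of -0.87, short of the difference of 1 asked of the scores, so whether such a loss contributes stays open. The S3 list holds 4 of the male-biased and 2 of the female-biased genes, and female-biased genes fell too, so loss of that segment's transcripts stays open.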
